A study of Caenorhabditis elegans with 2 samples.

How the data were processed

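Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been carried out on whole hermaphrodite Caenorhabditis elegans of strain OP484, per the labels. The animals carry a transgene for the nuclear hormone receptor NHR-90 fused to a green fluorescent protein tag, and chromatin bound to the tagged protein was recovered with an antibody against that tag, per the sample descriptions in the labels. A separate antibody field in the labels names nhr-90 instead, and one label describes the tag as GFP with FLAG. The animals were young adults, collected 64 h after synchronization as starved first-stage larvae. The labels give 2 biological replicates of this 1 group, so no comparison between groups of samples was made. A control experiment named in the labels was not analysed here.

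The deposited files are narrowPeak lists on 2 genome builds, ce11 and ce10. For each build there is a list per replicate, a list called from both replicates together, and a list of peaks that passed a threshold on the irreproducible discovery rate (IDR, a measure of how far replicate lists rank peaks alike), per the text records deposited with the samples. The list from both replicates, called the pooled list here, is titled as peaks and background that were input for IDR. Its lower peaks may therefore be background and are not taken as weaker binding sites. The peak caller, the aligner, their versions, the treatment of reads that map to several places and the IDR threshold are not given in the sources used here. The peak signal is the authors' value for each peak, from the narrowPeak signal column, and was used to rank or describe peaks within a list. Between lists, it was compared by rank correlation for the replicates, and at equal rank for the pooled lists of the 2 builds. The deposited −log10 q-value had a highest value of 2.79 that 2783 pooled peaks shared, all 1441 IDR peaks among them, so it did not rank the peaks. The summit is the deposited offset from the peak start. The 1441 IDR peaks have 1424 distinct intervals, since some differ in summit only, and form 1373 regions once overlapping intervals are merged. The numbers of reads are unknown here, so intervals cover the counting of peaks only. The pooled list and the replicate 1 list each held 30000 peaks on both builds, and the replicate 2 list held 26622 on ce11.

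Chromosome sequences and gene models came from WBcel235, the assembly that ce11 coordinates follow, with Ensembl release 115 for genes and RefSeq for the amino acid of tRNA genes, which matched 607 of 612 tRNA genes by position. All ce11 peaks ended within its chromosome lengths. No coordinate was converted between builds, and ce10 lists entered comparisons by count, chromosome name, signal at equal rank, and overlap or signal correlation within ce10. Coordinates are 1-based on ce11.

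A summit was placed at a gene start when it lay between 1000 bp upstream and 500 bp downstream of an annotated start of a protein-coding transcript. Shares of summits were compared by Fisher's exact test, two-sided, with the 27930 pooled nuclear peaks that share no base with an IDR peak. Odds ratios had 0.5 added to each cell, with Wald 95% intervals. Chromosome shares were compared by a two-sided exact binomial test with the share of protein-coding genes, with exact 95% intervals. Each of 35 gene lists was compared with all other nuclear protein-coding genes by Fisher's exact test, and 17 sequence motifs and 2080 6-base words were compared between the 100 bp at the summit and 100 bp centred 500 bp away on the same chromosome by an exact McNemar test. Benjamini-Hochberg adjustment was applied within each of these families, and calls were made at an adjusted p under 0.05. The overlap of the lists was compared with 1000 circular shifts of the replicate lists within each nuclear chromosome, which allow a smallest p of 0.0010. Peaks are not replicates: these p-values treat peaks or genes as units and do not measure the spread between animals. Each share was therefore also computed from the same number of highest-signal peaks of each replicate alone.

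The planned tests, gene lists, motifs and alternatives were fixed before the data were examined. All comparisons with tRNA, snoRNA and snRNA genes were chosen after the peaks were seen. The plan also did not list the tests of chromosomes other than X, the comparisons with other non-coding genes, or the comparison of GC content. Genes were named by a rule fixed before the data were examined. It takes the 15 IDR peaks with the highest signal, each with its nearest protein-coding start, and the 4 members with the highest-ranked peak of each list with more peaks. Of lists with fewer peaks it takes members with a peak among the first 100, and it adds nhr-90, unc-119 and the 10 6-base words with the smallest p. The 15 strongest nuclear peaks were added after the values were seen. The deposited score column holds 0 throughout, so the stricter set was the 720 IDR peaks with the highest signal.

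Alternatives covered the peak set, each replicate alone, the promoter window, the background, the motif window, dinucleotide shuffles, the overlap that counts as shared and the ce10 lists. Sets with overlapping peaks merged, with 2232 pooled peaks, and without summits near small-RNA genes were added after the data were seen. The tests were tried on simulated data of 1441 random positions. A motif planted in 19.6% of windows was found at 20.0 percentage points over the flanks, and its 6-base word ranked 1 of 2080. Summits put at 80 nuclear hormone receptor genes gave 1 called list of 35, and 0 lists, 0 of 17 motifs and 0 words were called without planting. Random positions have no built-in difference in base composition from their flanks, whereas the IDR summits had a mean GC content of 48.3% against 36.1%. The simulation therefore does not cover motif or word calls that arise from base composition. It also does not cover gene sequences repeated among the summits. The planted motif difference was larger than any reported for a motif below, so the simulation does not show that smaller differences would be found. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.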

Results

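Genomic sites recovered with tagged NHR-90, a nuclear hormone receptor of C. elegans, were mapped in whole young adult hermaphrodites in 2 biological replicates. The IDR list on ce11 held 1441 peaks with a median width of 450 bp, 1422 on nuclear chromosomes and 19 on the mitochondrial genome. These were the 1441 pooled peaks with the highest signal, down to a signal of 98.9. The ce10 list held 2232 peaks, down to a signal of 76.2. Pooled signals at the same rank differed by at most 0.928% between the builds over those ranks, and the 2 IDR lists ended at different ranks.

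Nearly all IDR peaks overlapped a peak in each replicate list. Of the 1441 IDR peaks, 1423 (98.8%) shared at least 1 bp with a peak of each replicate list. Of the nuclear peaks 98.9% did, against 3.86% on average and 5.42% at most in circular shifts (shift permutation p = 0.0010, the smallest that 1000 shifts can give). The IDR list derives from these lists, so this overlap describes their construction. Peak signal in replicate 1 and replicate 2 had a Spearman rho of 0.626 across 1423 peaks of all classes together, which are not independent replicates. Among each replicate's own strongest nuclear peaks, 71.5% of those of replicate 1 overlapped those of replicate 2.

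**Figure D1:**
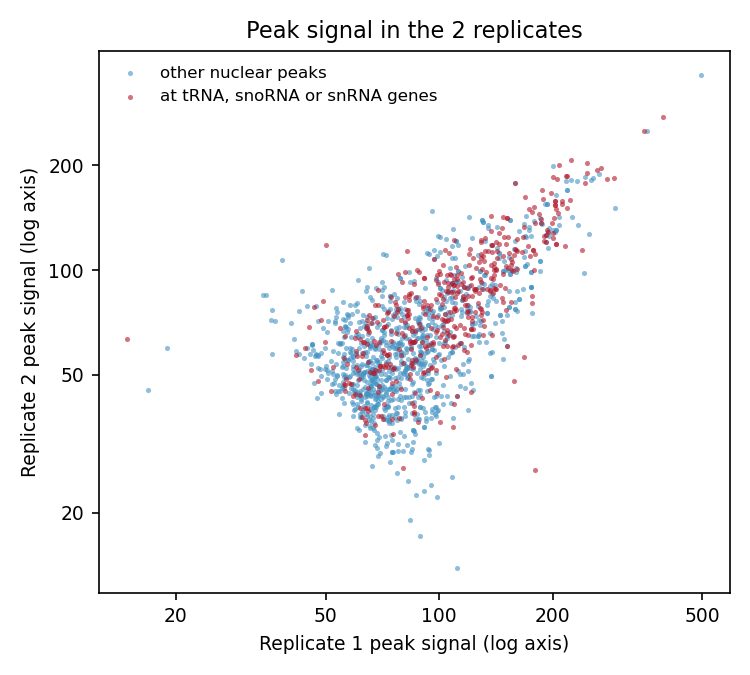
Peak signal of replicate 1 (x axis) against replicate 2 (y axis), both on log axes, for nuclear IDR peaks with a peak in both replicate lists. Each point is a peak, red within 100 bp of a tRNA, snoRNA or snRNA gene and blue elsewhere, and rho was 0.612 across 1406 peaks.

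Of the 15 peaks with the highest signal, 14 lay on the mitochondrial genome and 1 lay upstream of rpl-3. The first had a signal of 2871 at bases 12098 to 12658 of the mitochondrial genome, and the second, at bases 5858 to 6379, lay nearest to the start of COX3, a subunit of cytochrome c oxidase. Others lay nearest to ND1, a subunit of complex I, at bases 2045 to 2522 and 930 to 1269. The peaks ranked 5 and 9, on the mitochondrial genome, overlapped no peak of replicate 1. The first peak and the remaining mitochondrial peaks of the 15 were nearest to WBGene00010967, WBGene00000829, WBGene00010961, WBGene00010964, WBGene00010966, WBGene00010965 and WBGene00010960. The peak of rpl-3 (WBGene00004414), which encodes a protein of the large ribosomal subunit, ranked 11 with a signal of 856. It spanned III from 3867375 to 3867808, with an intergenic summit at offset -267 bp from the start, and had signals of 496 in replicate 1 and 364 in replicate 2.

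The strongest nuclear peaks, listed after their values were seen, lay mostly at genes for small non-coding RNAs. The second nuclear peak, with a signal of 666, had its summit at V 12303624 in an intron of frm-7, within 100 bp of the snoRNA genes C51F7.3 and C51F7.4. A summit at V 8500575, in an intron of pxn-1, lay at the snoRNA gene ZK994.7 with a signal of 605. Further snoRNA genes at these peaks were W03C9.9, C10C6.8, Y75B12B.12, T19B4.8 and T06C12.16, with signals between 442 and 480.5. A summit at I 13463972 lay in an intron of ints-8 at rpr-1, which encodes the RNA of RNase P, with a signal of 433. Protein-coding starts within 500 bp of such a summit and without an annotated non-coding gene within 100 bp were those of rpl-3, rpl-15, serp-1.1 and tasp-1, the last with a signal of 607 and an offset of -54 bp.

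Genes for tRNAs, snoRNAs and snRNAs lay within 100 bp of 466 of the 1422 nuclear IDR summits (32.8%), against 204 of 27930 lower pooled summits (0.730%). The odds ratio was 66.1 (95% interval 55.4 to 78.9; Fisher's exact test gave a p too small to be represented). The share was 31.5% in the strongest peaks of replicate 1 and 32.2% in those of replicate 2. Genes for tRNAs accounted for 384 summits (27%, odds ratio 130, 101 to 166), snoRNA genes for 67 (4.71%, odds ratio 18.6, 13.3 to 26.0) and snRNA genes for 15 (1.05%, odds ratio 5.96, 3.37 to 10.5). Of 612 nuclear tRNA genes, 399 (65.2%, exact interval 61.3 to 69.0) had an IDR summit within 100 bp, against 0.452% on average and 1.63% at most in circular shifts of the summits. A summit also lay within 100 bp of 65 of 346 snoRNA genes (18.8%) and 13 of 129 snRNA genes (10.1%). A tRNA gene whose sequence occurs once had a peak in 61 of 140 cases (43.6%). One with identical copies had a peak in 338 of 472 (71.6%, Fisher's exact p = 2.70e-09). Each identical copy counted as a separate gene in this test, though copies of 1 sequence may not vary independently. Among other non-coding classes, genes annotated only as ncRNA lay near 394 summits (27.7%, odds ratio 9.79, 8.58 to 11.2), though some of these summits also lay at snoRNA or tRNA genes. Genes for miRNAs lay near 6 summits (odds ratio 5.96, 2.47 to 14.3, Fisher's exact test, adjusted p = 0.00252), and the 2.30% of them with a summit lay below the highest share in shifts (2.68%, shift permutation p = 0.00799). Those for lincRNAs lay near 9 (odds ratio 2.45, 1.24 to 4.81, Fisher's exact test, adjusted p = 0.0290; shift permutation p = 0.0819), and those for piRNAs, short germline RNAs, near 6 (odds ratio 1.02, 0.465 to 2.26).

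**Figure D2:**
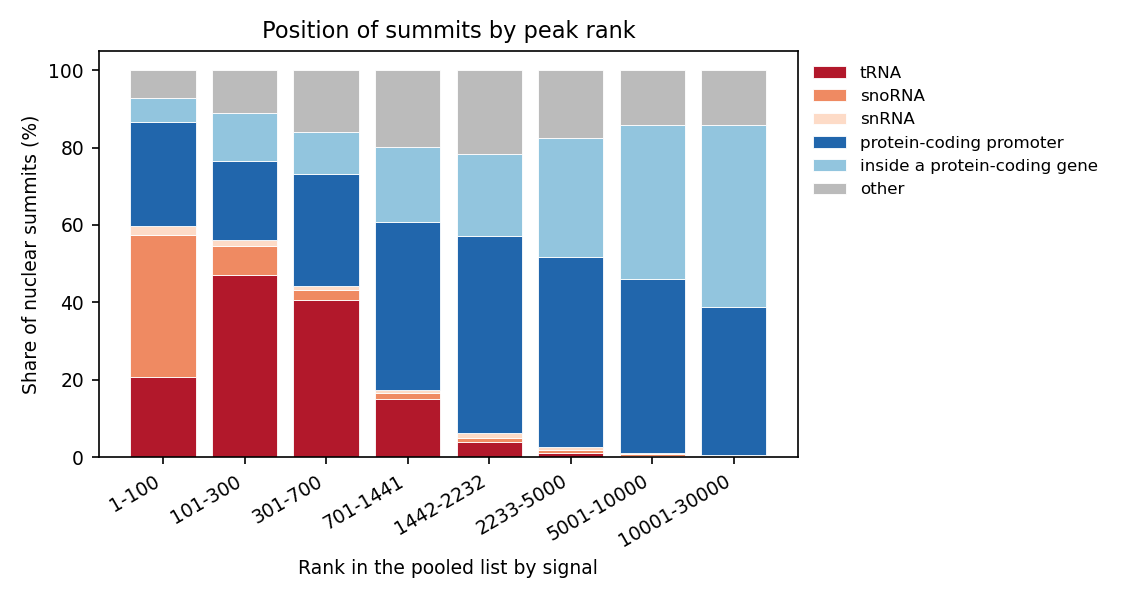
Share of nuclear summits (y axis, %) by rank in the pooled list (x axis), coloured by position within 100 bp of a tRNA, snoRNA or snRNA gene, else from 1000 bp upstream to 500 bp downstream of a protein-coding start, else inside a protein-coding gene, else elsewhere. snoRNA genes held 36.6% of the 82 nuclear summits in the first 100 ranks. Genes for tRNAs held 47% of those at ranks 101 to 300 and 14.98% of those at ranks 701 to 1441, where the ce11 IDR list ends.

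Summits lay at the 5′ part of tRNA genes and upstream of snoRNA genes. At tRNA genes, whose median length was 72 bp, the median summit was 14 bp downstream of the 5′ end (interquartile range 5 to 47). At snoRNA genes the median summit offset was -29 bp (-49 to -8), and 55 of 67 summits (82.1%) were upstream of the gene. By amino acid, genes for aspartate tRNA had a peak in 25 of 27 cases (92.6%) against 64.5% of other tRNA genes (Fisher's exact test, adjusted p = 0.0309). Identical copies counted as separate genes here. The 19 other amino acid groups of the 20 tested did not pass, and their shares ran from 45% of histidine to 82.4% of threonine tRNA genes.

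**Figure D3:**
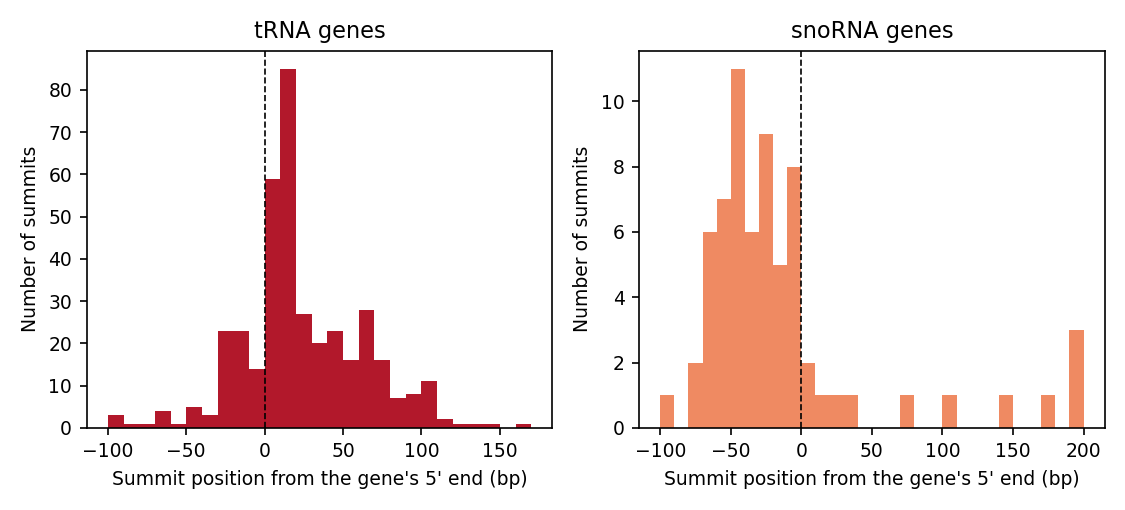
Number of IDR summits (y axis) by distance in bp from the 5′ end of the tRNA gene (left) or snoRNA gene (right), with the 5′ end as a dashed line at 0 and positive values inside or downstream of the gene. The tRNA summits gather just inside the gene (median 14 bp) and the snoRNA summits upstream of it (median -29 bp).

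Chromosome X held 372 of the 1422 nuclear peaks (26.2%, exact interval 23.9 to 28.5), against 13.7% of protein-coding genes (exact binomial p = 1.53e-35) and 17.7% of nuclear genome length (exact binomial p = 1.60e-15). It held 26.4% of the strongest peaks of replicate 1 alone and 25.8% of those of replicate 2 alone. Chromosome V, with 25% of genes, held 14.98% of peaks (adjusted p = 1.28e-19 by the exact binomial test), and chromosome II held 13.2% against 17.3% (adjusted p = 6.81e-05). The deficit on V was smaller against its 17.98% of the lower pooled peaks and 20.9% of genome length, which were not tested. For II these shares were 17.6% and 15.2%. Chromosome III held 16.7% against 13.2% of genes (adjusted p = 2.94e-04, exact binomial test), but 17.6% of the lower pooled peaks lay there, so the direction turns with the background. Of the tRNA genes, 276 lay on X, and 64.9% of these had a peak against 65.5% of autosomal tRNA genes (odds ratio 0.973, 0.697 to 1.36, Fisher's exact p = 0.932). Without summits within 100 bp of small-RNA genes, X held 195 of 956 peaks (20.4%, 17.9 to 23.1), an excess that was smaller against genome length (exact binomial p = 0.0305) than against genes (1.05e-08).

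**Figure D4:**
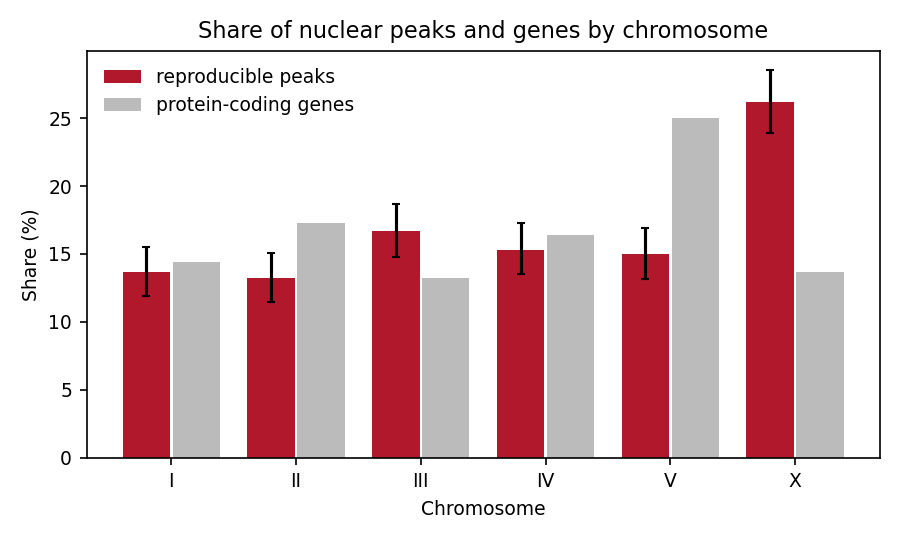
Share of nuclear IDR peaks (red, with exact 95% intervals) and of protein-coding genes (grey) on each chromosome (x axis), in percent (y axis). X holds 26.2% of peaks and 13.7% of genes, and V holds 14.98% of peaks and 25% of genes.

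In the central 1 of 3 equal parts of each autosome lay 39.3% of 1050 autosomal summits (36.4 to 42.4), against 38.1% of autosomal gene starts, which was no detectable difference (exact binomial p = 0.427). Of the lower pooled summits 34.3% lay there, and against that background the share of IDR summits was higher (exact binomial p = 6.38e-04).

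Of the 1422 nuclear summits, 648 (45.6%) lay in the promoter window of a protein-coding gene, against 41.0% of lower pooled peaks (odds ratio 1.20, 1.08 to 1.34, Fisher's exact p = 8.30e-04). The share was 46.5% in replicate 1 alone and 44.1% in replicate 2 alone. It rose to 52.3% without summits near small-RNA genes, against 41.1% of the corresponding background. With a window of 500 bp upstream of the start it was 27% against 18.1% (Fisher's exact p = 5.80e-16), and random positions gave 32.1% with the main window (p = 3.10e-24, Fisher's exact test). With a window from 2000 bp upstream to 1000 bp downstream the call was lost, at 63.2% against 61.4% (Fisher's exact p = 0.171), as it was among the 720 strongest peaks, at 41.7% against 41.4% (p = 0.907, Fisher's exact test). The 355 nuclear peaks with the highest signal lay at gene starts in 40.8% of cases and the 355 with the lowest in 52.4% (odds ratio 0.628, 0.467 to 0.845, Fisher's exact p = 0.00259). The difference of -11.55 percentage points was -6.46 in the strongest peaks of replicate 1 alone (p = 0.0968, Fisher's exact test), -4.57 among the 720 strongest peaks (p = 0.450) and -1.67 without small-RNA gene summits (p = 0.784).

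Ribosomal protein genes carried peaks more often than other genes. Of 81, 23 (28.4%) had a summit at the start, against 3.52% of other protein-coding genes (odds ratio 11.01, 6.78 to 17.9, Fisher's exact test, adjusted p = 2.31e-13). After rpl-3 the members with the highest-ranked peaks were rpl-15 (WBGene00004427, IV 653480 to 654576), rpl-20 (WBGene00004432, IV 4749123 to 4749778) and rpl-35 (WBGene00004449, III 7855134 to 7855646). Their signals were 445, 311 and 306, and all 3 summits were intergenic, at -348, -288 and -448 bp from the start. No tRNA, snoRNA or snRNA gene lay within 100 bp of the summits of these 4 genes, and without summits near such genes 23 members still had a peak (odds ratio 14.1). The odds ratio was 10.6 in replicate 1 alone, 10.1 in replicate 2 alone and 4.96 against genes with any pooled-list peak (adjusted p = 9.12e-07, Fisher's exact test).

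Genes for subunits of the vacuolar ATPase, the proton pump of lysosomes and other acidic compartments, had a peak in 4 of 20 cases (odds ratio 7.29, 2.56 to 20.7, Fisher's exact test, adjusted p = 0.0454). The peak of vha-13 (WBGene00013025, V 14351709 to 14354422) had a signal of 211 and its summit at offset -535 bp, in an annotated 3′ UTR. Those of vha-1 (WBGene00006910, III 9781254 to 9781763) and vha-8 (WBGene00006917, IV 6791074 to 6792455) were intergenic, with signals of 197 and 130, and that of vha-2 (WBGene00006911, III 9782164 to 9783224) was in a coding exon at 66 bp with a signal of 132. The call was lost against genes with any pooled-list peak (odds ratio 3.30, adjusted p = 0.618, Fisher's exact test). It was also lost among the 720 strongest peaks, with a window of 500 bp upstream of the start and with the nearest start alone, where fewer peaks or genes entered and the odds ratios were 7.90, 6.34 and 6.435.

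Chemoreceptor genes had a peak in 7 of 1264 cases (0.554%, odds ratio 0.150, 0.0728 to 0.308, Fisher's exact test, adjusted p = 7.78e-12), and genes for F-box and MATH-BTB proteins in 4 of 395 (odds ratio 0.301, 0.119 to 0.765, adjusted p = 0.0282). Among the first 100 ranks the one chemoreceptor peak was that of sre-23 (WBGene00013957, I 8256301 to 8258939), with a signal of 391, an intergenic summit at offset -616 bp and a small-RNA gene within 100 bp of its summit. Against genes with any pooled-list peak neither list was called (adjusted p = 0.868 and 0.876, Fisher's exact test). The F-box and MATH-BTB list was also not called among the 720 strongest peaks (odds ratio 0.513, adjusted p = 0.778, Fisher's exact test), with the window of 500 bp upstream (odds ratio 0.292) or with the nearest start alone (odds ratio 0.363).

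The remaining 31 lists did not pass. Nuclear hormone receptor genes had a peak in 10 of 269 cases (3.72% against 3.62% of other genes, odds ratio 1.08, 0.579 to 2.01). Cytochrome P450 genes had one in 2 of 74, UDP-glucuronosyltransferases in 1 of 67 and glutathione S-transferases in 2 of 44. Cathepsin proteases had one in 4 of 25 (adjusted p = 0.0823, Fisher's exact test), histones in 7 of 72 (0.0888), and heat-shock proteins in 3 of 22 (0.190). Some histone genes shared 1 peak but counted separately: his-59 with his-60, his-61 with his-62, and his-67 with his-68. Without summits near small-RNA genes, cathepsins and histones were called (odds ratios 7.10 and 3.89, each with adjusted p = 0.0336, Fisher's exact test). Tissue markers were not called in the full set and differences between tissues were not tested. A peak was found at 2 of 21 intestine, 1 of 25 germline and 1 of 18 pharynx markers, and at 0 of 22 neuron, 0 of 22 body wall muscle and 0 of 23 hypodermis markers. The strongest peaks of replicate 2 alone gave 8 lists with more peaks, adding heat-shock proteins, stress and immune regulators, intestine markers, insulin and lipid signalling regulators, cathepsins and histones to the 2 above. Those of replicate 1 alone gave 3, adding intestine markers (5 of 21, odds ratio 8.64, adjusted p = 0.0103, Fisher's exact test). Intestine markers were also called with 2232 pooled peaks (6 of 21, odds ratio 6.89, adjusted p = 0.00461, Fisher's exact test). So were stress and immune regulators (8 of 24, odds ratio 8.48), insulin and lipid signalling regulators, histones and heat-shock proteins (adjusted p from 3.31e-04 to 0.0254, Fisher's exact test). In all, 723 protein-coding genes (3.62% of 19973) had a summit at a start, and 575 did without summits near small-RNA genes.

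**Figure D5:**
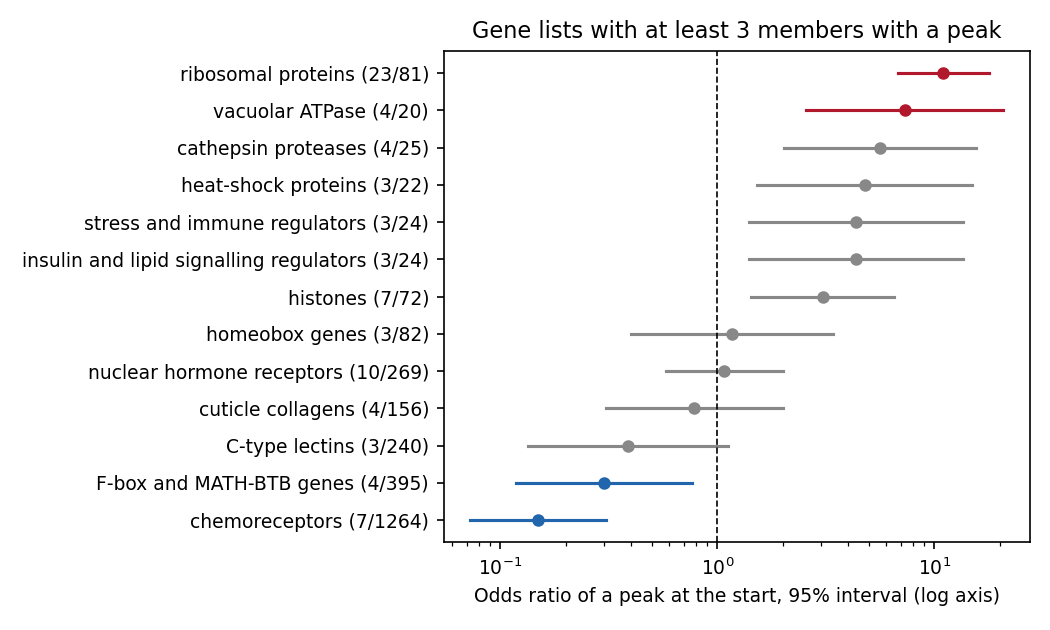
Odds ratio of a peak at the start (x axis, log axis) with its 95% interval for the gene lists with at least 3 members with a peak, red for called higher, blue for called lower and grey for not called. Counts with a peak and of all members follow each name, and ribosomal proteins stand at 11.01 and chemoreceptors at 0.150.

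No IDR peak lay within 1000 bp or 5000 bp of nhr-90 (WBGene00003680, V 610512 to 612513) or of unc-119 (WBGene00006843, III 10902641 to 10908935), a common rescue marker of transgenic strains. Within 1000 bp of nhr-90 the best peak ranked 2817 in replicate 1, with a signal of 41.4, and 1047 in replicate 2, with a signal of 52.7. At unc-119 the best ranks were 7518 and 9338. In the pooled list the best ranks within 1000 bp were 12249 at nhr-90, with a signal of 29.9, and 8206 at unc-119.

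Sequence at the summits was richer in G and C than beside them, with a mean GC content of 48.3% (SD 7.87 across 1422 windows) against 36.1% (SD 8.97). The GA repeat GAGAGAG was found in 7.38% of summit windows and 2.25% of flanking windows, the E-box CACGTG in 5.41% and 1.76%, and the GC box GGGYGKG in 5.34% and 0.985% (exact McNemar test, adjusted p = 3.95e-10, 4.48e-07 and 1.51e-10). At the 466 small-RNA gene summits the GA repeat (1.93% against 2.36% of flanks) and the E-box (1.29% against 1.07%) were not called, while the GC box was (8.15% against 0.429%). At the 956 other summits the GA repeat was in 10.04%, the E-box in 7.43% and the GC box in 3.97%, all called. The GATA site WGATAR was less frequent at small-RNA gene summits than beside them (12.4% against 24.7%, adjusted p = 1.25e-05, exact McNemar test), and TGATAA was too (7.73% against 12.9%, adjusted p = 0.0343). With 1 summit for each of 188 distinct gene sequences, WGATAR kept its call (adjusted p = 0.00610, exact McNemar test). TGATAA lost its call there (5.85% against 13.8%, adjusted p = 0.0575, exact McNemar test). At the other summits TGATAA was more frequent (12.3% against 8.47%, adjusted p = 0.0161, exact McNemar test) and WGATAR was not called (23.1% against 18.8%, 0.0560). Differences between these sets of summits were not tested. The nuclear receptor site AGGTCA was found in 3.94% and 2.04% (adjusted p = 0.00981, exact McNemar test). The T-run, the TATA box and the homeodomain core TAATTA were less frequent at summits, by -7.59, -5.06 and -3.59 percentage points (adjusted p of 2.26e-14, 6.18e-07 and 7.20e-09, exact McNemar test). The direct repeat of receptor sites and the HNF4-type site were in 3 and 2 summit windows. Against dinucleotide shuffles the GA repeat and the E-box kept their calls, while those of AGGTCA (adjusted p = 0.734), the GC box (0.365) and TAATTA (0.133, exact McNemar tests) were lost and the T-run (1.27 points) and the TATA box (2.46 points) changed direction. The difference of AGGTCA, 1.90 points in the full set, was 1.71 among the 720 strongest peaks, with fewer windows and no call (adjusted p = 0.196, exact McNemar test). It was also not called in the strongest peaks of replicate 2 alone (1.27 points, adjusted p = 0.101, exact McNemar test) or without small-RNA gene summits (1.15 points, 0.209).

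Of 2080 6-base words, 624 were more frequent at summits and 389 less frequent. Words were not compared with dinucleotide shuffles, so these calls are not separated from the GC content of summits (48.3% against 36.1% in flanks). Windows at identical gene copies also counted separately. Among the 10 with the smallest p, AAAAAT, AAAATT, TAAAAA, AAAAAA, TTAAAA, AAATTA and TCAAAA were less frequent, AAAAAT in 18.4% of summit windows against 46.8% of flanks. CGAACC (14.7% against 1.76%), ACCACT (14.1% against 1.76%) and CACGCG (9.99% against 0.633%) were more frequent, with adjusted p from 1.37e-29 down to 1.75e-35 by the exact McNemar test. CGAACC matches part of the B box, an internal promoter element of tRNA genes. Without small-RNA gene summits 430 words were more frequent, CGAACC and ACCACT were not among the 40 with the smallest p, and ACGCAG (13.9% against 1.15%) and CGTCTC (15.7% against 2.41%) led those more frequent.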

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

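The test of mitochondrial coverage was chosen only after the peaks were seen. The mitochondrial genome, which no nuclear comparison uses, held 19 IDR peaks, and this brought it to notice. Their signals ran from 163 to 2871, with a median of 980, against 856 for the strongest nuclear peak. The replicate lists held 16 and 25 mitochondrial peaks, and in each the highest-ranked peak was mitochondrial. Many copies of mitochondrial DNA per cell are a candidate explanation. It was taken to need peaks over more than 50% of that genome that enter both replicates' lists. The peaks covered 44.0% of its 13794 bp, and those ranked 5 and 9 overlapped no peak of replicate 1. Coverage by listed peaks also depends on peak width and on where the list ends. It therefore does not measure copy number, and the explanation stays open. The control that could decide this explanation was not analysed here, and no biological explanation was tested.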

How the results depend on the processing

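Alternatives with merged peaks, 2232 pooled peaks or without small-RNA gene summits, and all those for the small-RNA share, were chosen after seeing the data. The X chromosome share (20.4% to 29.96%; p up to 0.0305, against genome length without small-RNA gene summits), the small-RNA gene share (19.3% to 48.9%) and replicate overlap (71.6% to 98.8%) kept their direction and side of the threshold under every alternative run, as did the ribosomal protein list (odds ratios 4.96 to 14.1). The number of IDR peaks was 2232 on ce10 and 720 in the stricter set, which is smaller by construction. In that set the promoter share was 41.7%, the strong-weak difference -4.57 percentage points, and 337 genes and 1 list were counted. The promoter share was 63.2% with the wide window. The strong-weak difference was -1.67 points without small-RNA gene summits, and between -11.02 and -6.46 with a single replicate. Genes with a peak numbered 418 with the window of 500 bp upstream and 1150 with 2232 pooled peaks. Lists with more peaks numbered 1 with that window, with the nearest start alone and against genes with a pooled-list peak, 4 without small-RNA gene summits, 7 with the wide window and 7 with 2232 peaks, and 3 to 8 with a single replicate. The ribosomal protein and vacuolar ATPase lists were called with each replicate alone. The chromosome centre share of 39.3% passed the threshold only against lower pooled peaks. Against dinucleotide shuffles the differences of the T-run (1.27 points, not past the threshold) and the TATA box (2.46 points) were reversed. Of the comparisons of called lists with an alternative, 31 kept and 9 lost the call. Of those of motifs, 55 kept and 6 lost it. Apart from the smaller set, the causes were not tested. No paired analysis was possible because the series holds 1 group. The unknown read depth limits every list, and the pooled and replicate 1 lists end at 30000 peaks.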

Other observations

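Genes outside the called lists that had a peak, named after their values were seen, include several regulators. Among nuclear hormone receptors, the peaks of nhr-255, nhr-68 and nhr-49, a regulator of fat metabolism, had signals of 235, 202 and 146, the first with a tRNA gene within 100 bp of its summit. Chaperone genes hsp-3, hsp-60 and hsp-1 had peaks with signals of 375, 220 and 167, and the stress regulators zip-2, xbp-1 and skn-1 of 228, 206 and 113. The yolk protein gene vit-2 had a signal of 181.

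In the following 2 patterns, the X share without small-RNA gene summits and its backgrounds, and the tests on 1 summit per distinct gene sequence, on tRNA genes unlike any other, and on a single replicate were chosen only after the result was seen. The excess on X was not explained by small-RNA genes alone: without their summits the X share was 20.4% (17.9 to 23.1), still above 13.7% of genes (exact binomial p = 1.05e-08), so tRNA genes may account for part of it. The size of the rest depends on the background, since X makes up 17.7% of genome length (exact binomial p = 0.0305) and holds 12.9% of the lower pooled peaks without such summits (7.25e-11). Explanations of the rest were not tested.

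For peaks at tRNA and snoRNA genes, a single replicate is excluded as the source, since the lower share was 0.980 of the higher. Reads shared between identical copies stay open as a part of the pattern, and were examined at tRNA genes only. Genes for tRNAs with 1 copy of their sequence had a peak less often than those with identical copies (61 of 140 against 338 of 472). The odds ratio was 0.307 (0.209 to 0.453, Fisher's exact p = 2.70e-09, with each identical copy counted as a separate gene). This difference may also reflect inactive single-copy genes. Still, 43.6% of the single-copy genes had a peak, against 1.63% at most for all tRNA genes in circular shifts. This argues against identical copies as the only source at tRNA genes. Reads shared between similar sequences are a separate question. Of 40 tRNA genes at least 5 edits from any other, 7 (17.5%, 7.34 to 32.8) had a peak, against 0.485% on average and 7.5% at most in circular shifts (shift permutation p = 0.0010, the smallest that 1000 shifts can give), but the lower end of the interval did not pass 7.5%, as excluding shared reads was set to need. Receptor sites as a biological explanation stay open: AGGTCA was in 5.79% of 466 summit windows against 2.36% of flanks, which passed the criterion written first (adjusted p = 0.0343, exact McNemar test), and over 188 distinct gene sequences the shares were 5.85% and 2.13%, as large a difference in fewer windows that did not pass (adjusted p = 0.336). The other receptor sites of that criterion, the direct repeat and the HNF4-type site, were in 0 of 466 summit windows and 0 of 466 flanks. The windows at these summits had a mean GC content of 50.2% against 35.2% in their flanks. The comparison of AGGTCA therefore does not separate the site from base composition. In the full set the difference of AGGTCA was 0.352 points against dinucleotide shuffles and was not called (adjusted p = 0.734, exact McNemar test). Open or highly transcribed chromatin, which a control would measure, was not tested.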
